A study of Gallus gallus with 14 samples.

How the data were processed

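Retinas of White Leghorn chicks were sampled after 6 days with a -10 D lens in front of the eye, fitted at 3 days of age, or as controls. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded total RNA kit after ribosomal RNA depletion. The submitters' processing notes name STAR, Partek and the genome build GRCg6a, without versions. The counting method, its strand setting and any gene filter are not given in the sources used here. The labels do not say that each library came from a different animal. The p-values therefore measure the spread between these 14 samples.

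The authors deposited 1 table of normalized values in CPM, for 18631 genes in 14 libraries. The values held 0.0001 added to every entry. The listed genes of a library held 31.7% to 34.2% of the total used for scaling, so that total also held reads outside them. Depth was read from the values. In each library, low values were multiples of 1 step, the value of 1 read, and the inverse of that step gave 32.3 to 42.6 M reads in total and 10.8 to 14.1 M reads in genes. Of the low non-zero values, 92.5% to 93.1% were whole numbers of reads within 0.02 of a read and the rest were fractions. The values were therefore not treated as whole reads and no count model was used. The pairs of libraries differed by more than counting noise (lowest chi-square per gene 6.47, where 1 is expected from counting alone), so each of the 14 was kept as 1 sample.

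Groups and replicate numbers were taken from the sample titles, and the groups share no replicate number. Values were transformed as log2(CPM + 1). Genes with at least 1 CPM in at least 7 of 14 samples were tested, 11132 in all. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. The groups were compared with limma (version 3.58.1, R version 4.3.3) with an intensity trend and no robust prior, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were fixed before the data were examined. Of 38 lists, 36 had at least 5 tested members. They were tested with limma's camera at a correlation of 0.01, with camera at an estimated correlation and with fry beside it. List scores, the mean over members of centred log2 values, and principal components were compared by exact two-sided permutation over all 3432 assignments of the samples to 7 and 7. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.

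Genes were named by a rule fixed before the data were examined. It took the 8 largest fold changes in each direction among genes past the threshold with a symbol and at least the median expression. It also took the 2 members with the smallest p in the direction of each list that camera called, the genes EGR1, VIP, GCG, PENK, TH, BMP2 and OPN1LW, among others, where tested, and genes past the threshold in the chick myopia list. Some genes that the rule took are not reported here, and counts of named genes cover all that it took. Other members of the clock, rod and cone lists, WDCP, C2orf71, LOC101749116, NDRG1, PTN, ABCA4, IMPG1, SCG2, CPLX1, MEIS2, SLC6A9, GJD2 and KCNH1 were named after their values were seen.

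Gene names are those of the deposited table. Of 18631 symbols, 15772 matched a name, gene number or synonym in the RefSeq gene table of assembly GRCg7b, which served for names of chromosomes and genes and not for coordinates. Start and stop are printed as deposited. The table does not say whether the stop base is included, so a boundary can be off by 1 base.

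The test was run on simulated reads for the comparison of lens against control, at the mean of each gene in control and the depth of each library, with 1 spread for all genes taken from the median control variance. With 11157 genes fitted and 200 changed genes, it recovered 37.9% of genes changed 1.2-fold, 100% of those changed 1.5-fold and 100% of those changed 2-fold. Of its 169 calls, 7.10% were false. Real genes differ in spread, so recovery for a given gene can be lower. A simulated list of 25 genes raised 1.15-fold was called by camera, and a list of 25 unchanged genes was not. Simulated genes were drawn independently and only 1 unchanged list was tried. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

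Alternatives (18 for gene results, 11 for camera and 9 for list scores) covered the pseudocount, the filter, 4 scalings, the prior, array weights, an exact permutation test per gene, thresholds, covariates for the code letter of the title (L or R, not explained in the labels) and for W-linked expression, autosomal genes only, and leaving out each library. Voom weights on estimated reads, a common sum over listed genes, and leaving out the 3 libraries without W-linked transcripts were added after seeing the data. The list of mitochondrial genome genes was not tested, because the table holds that genome as 4 features that match none of its members. The list of blood markers was not tested either, with 1 tested member.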

Results

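Retinal transcript levels were compared between White Leghorn chicks that wore a -10 D lens and control chicks, to ask which genes differ in the retina after 6 days of lens-induced myopia. A -10 D lens shifts the plane of focus behind the retina, and the growing chick eye elongates towards it. Lenses were fitted at the age of 3 days. The data comprised total RNA sequencing of 7 control retinas (57, 58, 59, 62, 63, 64 and 65) and 7 lens retinas (46, 47, 48, 51, 53, 54 and 55), 1 library per retina. Values were in CPM for 18631 genes on the chicken build GRCg6a, and 11132 genes were tested. Total depth, read from the smallest step between values, was 32.3 to 42.6 M reads per library, so that 1 CPM corresponded to 32.3 to 42.6 reads. Mean total depth was 35.6 M ± 2.31 (SD, n = 7) in control and 39.1 M ± 3.26 (SD, n = 7) in lens libraries.

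After 6 days of lens wear, the retina had higher transcript levels of the transcription factors NFIL3, PRDM1 and ARNTL, the lipase inhibitor G0S2 and the red cone opsin OPN1LW. It had lower levels of the retinol-binding protein RBP4, the retinol dehydrogenase RDH8, the clock gene PER3 and the rod phosphodiesterase subunit PDE6B. The changes were moderate. NFIL3 went from 27.7 CPM ± 6.80 (SD, n = 7) to 54.2 CPM ± 8.22 (SD, n = 7), and RBP4 went from 243 CPM ± 27.0 (SD, n = 7) to 127 CPM ± 24.2 (SD, n = 7). In limma at a Benjamini-Hochberg adjusted p under 0.05, 102 genes were higher and 205 were lower in lens retinas, 307 in all, and 1796 genes had an unadjusted p under 0.05. The median absolute log2 fold change of the 307 genes was 0.30, and 24 of them changed by at least 1.5-fold. The 7 lens and 7 control values did not overlap for 144 of the 307 genes and for 170 of all tested genes, where chance gives 0.0583% of genes. The split between directions depended on scaling. The median log2 fold change of all tested genes was -0.0378 with the values as deposited and -0.0021 with trimmed-mean (TMM) factors. The listed genes held 33.4% ± 0.454 (SD, n = 7) of the scaling total in control and 32.6% ± 0.660 (SD, n = 7) in lens libraries (exact permutation p = 0.0280, adjusted p = 0.123). Of the calls, 33.2% were higher with the values as deposited, 58% with trimmed-mean (TMM) factors, 59.6% with median-of-ratios factors, 56.3% after quantile normalization and 53.3% with a common sum over the listed genes. Without lens replicate 55, 324 genes were lower.

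Among the genes with the largest rises, NFIL3 (chromosome Z, 44356108 to 44370014), a leucine zipper repressor of clock output, rose by a log2 fold change of 0.97 ± 0.13 (SE, adjusted p = 2.56e-04). G0S2 (chromosome 26, 3140579 to 3141465) rose by 0.92 ± 0.14 (SE, adjusted p = 8.28e-04), from 9.52 CPM ± 2.26 (SD, n = 7) to 18.7 CPM ± 3.69 (SD, n = 7). PRDM1 (chromosome 3, 68347905 to 68446169), a repressor that acts in photoreceptor fate, had the smallest adjusted p of the genes named by the rule, with a log2 fold change of 0.81 ± 0.072 (SE, adjusted p = 1.45e-05). It went from 22.1 CPM ± 2.53 (SD, n = 7) to 39.4 CPM ± 3.79 (SD, n = 7). CD82, a tetraspanin (chromosome 5, 22211473 to 22245405), rose by 0.71 ± 0.11 (SE, adjusted p = 1.16e-03). In all 7 lens retinas each of these 4 genes lay above every control. CACNA2D4 (chromosome 1, 60966651 to 61086781, minus strand), an auxiliary calcium channel subunit of photoreceptors, went from 68.2 CPM ± 8.77 (SD, n = 7) to 111 CPM ± 10.7 (SD, n = 7). LRTM2 (chromosome 1, 60983371 to 61016011, plus strand), which lies inside CACNA2D4 on the other strand, went from 14.2 CPM ± 1.6 (SD, n = 7) to 8.76 CPM ± 0.873 (SD, n = 7). The strand setting of the counting was not given in the sources used here, so the values of these overlapping genes are uncertain.

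Among the genes with the largest falls, RBP4 (chromosome Z, 53612243 to 53617574) had a log2 fold change of -0.95 ± 0.10 (SE, adjusted p = 7.78e-05) and was below every control in all 7 lens retinas. This is the gene that RefSeq also calls RBP4B, and not RBP4A on chromosome 6. RDH8 (chromosome 8, 14341966 to 14351136), which reduces all-trans-retinal in outer segments, had -0.75 ± 0.18 (SE, adjusted p = 0.0306) and was below every control in 5 of 7 lens retinas. Its call was lost with TMM factors (adjusted p = 0.0578) and with a robust prior (adjusted p = 0.082), within a range of 0.0163 to 0.106 over its alternatives, and in 8 of the 14 fits that left out 1 library. SLC24A4, a sodium, calcium and potassium exchanger (chromosome 5, 44851002 to 44936137), went from 322 CPM ± 45.2 (SD, n = 7) to 206 CPM ± 9.16 (SD, n = 7). SLC4A11, a membrane transporter (chromosome 4, 88863709 to 88993489), went from 15.9 CPM ± 1.48 (SD, n = 7) to 9.99 CPM ± 1.12 (SD, n = 7). WDCPL (chromosome 3, 104129233 to 104132010) went from 47 CPM ± 6.48 (SD, n = 7) to 30.7 CPM ± 3.92 (SD, n = 7). Its nearby related gene WDCP (chromosome 3, 104100477 to 104108162), named after its values were seen, went the other way, from 13.3 CPM ± 1.71 (SD, n = 7) to 20 CPM ± 1.73 (SD, n = 7). Their sum was 60.2 CPM ± 6.24 (SD, n = 7) in control and 50.7 CPM ± 4.07 (SD, n = 7) in lens retinas. Reads may have been shared between these copies, so both values are uncertain.

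Genes of the circadian clock and melatonin list changed in opposite directions. Of 25 tested members, 5 rose, 6 fell and 14 did not pass the test, and 14 passed when adjusted over the list alone. The 5 that rose were NFIL3, ARNTL and ARNTL2 (BMAL-type activators of the clock), NPAS2 (a partner of BMAL proteins) and TPH1 (tryptophan hydroxylase, which opens the serotonin and melatonin pathway). The 6 that fell were PER3, PER2, CRY2, BHLHE41 and NR1D2, which repress clock-driven transcription, and HLF, a clock-controlled activator. ARNTL (chromosome 5, 7819805 to 7864577) went from 27.9 CPM ± 5.93 (SD, n = 7) to 47.4 CPM ± 2.80 (SD, n = 7), with a log2 fold change of 0.77 ± 0.10 (SE, adjusted p = 2.47e-04). TPH1 (chromosome 5, 12654570 to 12667396) went from 10.1 CPM ± 0.759 (SD, n = 7) to 17.3 CPM ± 2.55 (SD, n = 7). PER3 (chromosome 21, 291189 to 310410) went from 58.2 CPM ± 8.36 (SD, n = 7) to 34.2 CPM ± 3.11 (SD, n = 7), with a log2 fold change of -0.74 ± 0.082 (SE, adjusted p = 7.78e-05). PER2 (chromosome 9, 5654602 to 5695660) went from 239 CPM ± 19.2 (SD, n = 7) to 176 CPM ± 13.3 (SD, n = 7), with a log2 fold change of -0.44 ± 0.056 (SE, adjusted p = 2.13e-04). The lens and control values of 9 of these 11 genes did not overlap. The list as a whole had no single direction (camera adjusted p = 0.976). CRY2 lost its call with TMM factors (adjusted p = 0.0691), median-of-ratios factors (0.0761), quantile normalization (0.0809) and a common sum over genes (0.0579). The labels give no time of day for tissue collection.

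**Figure D1:**
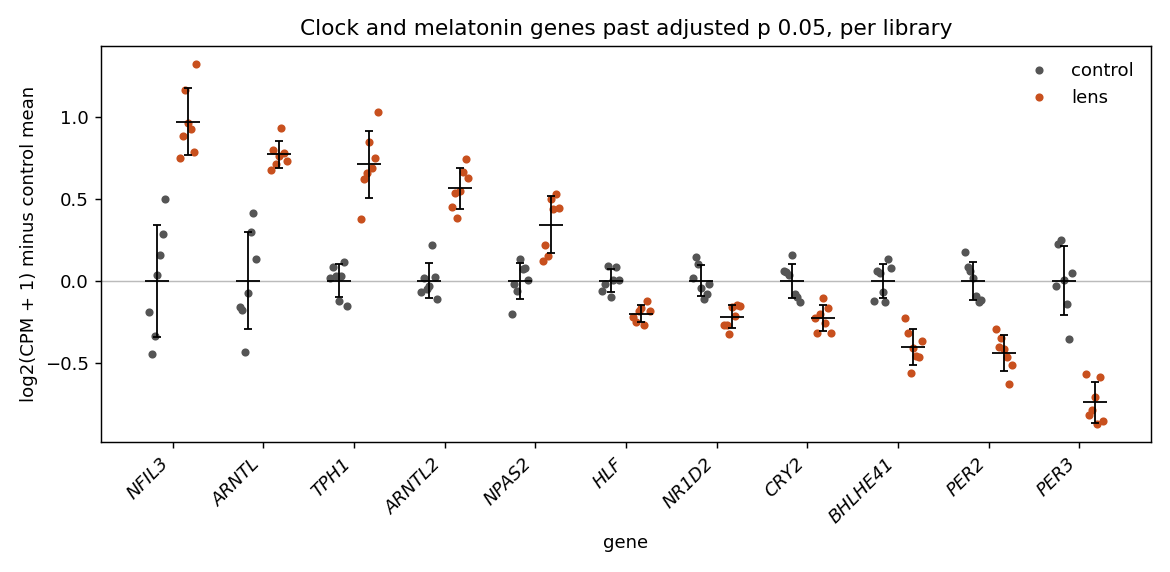
Each point is 1 library, with the 7 control libraries in grey and the 7 lens libraries in orange, for the 11 clock and melatonin genes past an adjusted p of 0.05. The vertical axis is log2(CPM + 1) minus the control mean of that gene, black bars give the mean ± SD, and the 5 genes from NFIL3 to NPAS2 lie higher in the lens libraries while the 6 from HLF to PER3 lie lower.

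Photoreceptor genes also changed in both directions. In the rod phototransduction list, 2 of 19 tested members rose, 5 fell and 12 did not pass (9 passed when adjusted over the list alone). In the cone phototransduction and opsin list, 1 of 16 rose, 6 fell and 9 did not pass (10 passed when adjusted over the list alone). OPN1LW, on an unplaced scaffold (194473 to 214895), went from 133 CPM ± 26.5 (SD, n = 7) to 224 CPM ± 68.7 (SD, n = 7), a log2 fold change of 0.72 ± 0.16 (SE, adjusted p = 0.0176), and 5 of 7 lens retinas lay above every control. Its call was lost with a robust prior (adjusted p = 0.0572) and in the exact permutation test per gene (adjusted p = 0.0649), within a range of 0.00995 to 0.0649 over its alternatives. The other 2 that rose were CNGB1, a subunit of the rod cyclic nucleotide-gated channel, and GUCA1B, a guanylate cyclase activator. Among those that fell, PDE6B (chromosome Z, 53573478 to 53602211) went from 91.6 CPM ± 10.8 (SD, n = 7) to 56.3 CPM ± 10.2 (SD, n = 7). NR2E3, a rod transcription factor near the lower limit of the test, went from 2.57 CPM ± 0.626 (SD, n = 7) to 1.07 CPM ± 0.208 (SD, n = 7). NR2E3 overlaps MYO9A on the other strand, which measured 40.0 CPM in control and 34.7 CPM in lens retinas. The strand setting was not given, so the NR2E3 value is uncertain, and its log2 fold change ranged from -1.23 to -0.31 over its alternatives. The other members of the rod list that fell were RP1, MAFA and RGS9. The cone opsin kinase GRK7 (chromosome 9, 10421447 to 10446325) had a log2 fold change of -0.52 ± 0.058 (SE, adjusted p = 7.78e-05), and the cyclase activator GUCA1C (chromosome 1, 88957447 to 89017340) had -0.50 ± 0.053 (SE, adjusted p = 7.78e-05). GRK7 overlaps ATP1B3 on the same strand, which measured 115 CPM in control and 110 CPM in lens retinas. The cone arrestin ARR3, the channel subunit CNGA3, the phosphodiesterase PDE6C and the exchanger SLC24A2 fell as well. RGS9 and SLC24A2 lost their calls with every scaling alternative tried, and each in 9 of the 14 fits that left out 1 library. With the 4 other scalings 3 or 4 rod members and 2 cone members were higher, and 4 rod and 5 cone members were lower.

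**Figure D2:**
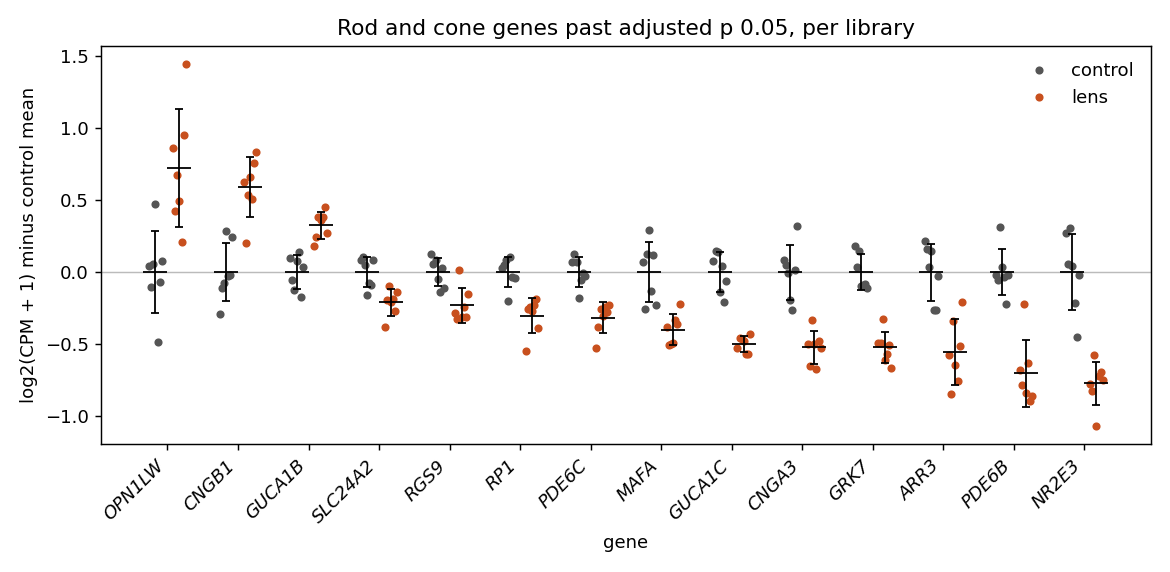
Each point is 1 library, with the 7 control libraries in grey and the 7 lens libraries in orange, for the 14 rod and cone genes past an adjusted p of 0.05. The vertical axis is log2(CPM + 1) minus the control mean of that gene, black bars give the mean ± SD, and OPN1LW, CNGB1 and GUCA1B lie higher in the lens libraries while the other 11 genes lie lower.

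Lists of amacrine and ganglion cell markers, synaptic vesicle genes, channels and glutamate receptors lay lower in lens retinas at a preset correlation in camera, and none of them passed with an estimated correlation (adjusted p = 0.514 to 0.717). Lists of bipolar, horizontal, starburst and dopaminergic cells did not pass in camera (adjusted p = 0.976 each), with medians of 0.02, 0.00, -0.03 and -0.10. The dopaminergic score passed as lower (exact permutation adjusted p = 0.0336) and lost that call with TMM factors (exact permutation adjusted p = 0.264) and in 6 of the 14 tests that left out 1 library. With camera at a preset correlation of 0.01, 9 of 36 tested lists passed, 8 of them lower and 1 higher, and 0 passed with an estimated correlation. Fry, which does not compare a list with other genes, called 13 lists, all lower, and these 8 were among them. The synaptic vesicle and release list had 7 of 32 members lower, 0 higher and 25 that did not pass (15 passed when adjusted over the list alone), with a camera adjusted p of 0.0062 and an adjusted p = 0.644 with an estimated correlation. With each of the 4 other scalings 4 members were lower. The list included the complexin CPLX4, found at photoreceptor and bipolar ribbon synapses, which went from 92.9 CPM ± 5.96 (SD, n = 7) to 71 CPM ± 7.28 (SD, n = 7), and the vesicle recycling enzyme SYNJ1, which went from 151 CPM ± 8.90 (SD, n = 7) to 127 CPM ± 6.86 (SD, n = 7). Of amacrine cell markers with GABA and glycine genes, 4 of 17 fell, 1 rose and 12 did not pass (7 passed when adjusted over the list alone). The camera adjusted p was 0.00689, and the adjusted p = 0.514 with an estimated correlation. The fallen members included the vesicular GABA and glycine transporter SLC32A1, at -0.36 ± 0.081 (SE, adjusted p = 0.0207), and the transcription factor TFAP2B, at -0.21 ± 0.046 (SE, adjusted p = 0.0178). The other members that fell were MEIS2 and SLC6A9, and GJD2 was the member that rose, all 3 named after their values were seen. Only 1 member of the list was lower with TMM factors, median-of-ratios factors or a common sum over genes, and 0 after quantile normalization. With voom weights 4 members were lower and 0 higher. Without the 3 libraries described below that lack W-linked transcripts, 0 members were lower and 0 higher. SLC32A1 and TFAP2B lost their calls after quantile normalization (adjusted p = 0.053 and 0.0784) and without those 3 libraries (adjusted p = 0.0877 and 0.0778).

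In the voltage-gated ion channel list, 3 of 40 fell, 1 rose and 36 did not pass (9 passed when adjusted over the list alone), with a camera adjusted p of 0.0062 and an adjusted p = 0.562 with an estimated correlation. That call was lost with a filter of 10 CPM (adjusted p = 0.202). The delayed rectifier channel KCNB2, at -0.25 ± 0.047 (SE, adjusted p = 0.00461), fell, as did KCNH1, named after its values were seen, and CACNA2D4 was the member that rose. In the glutamate receptor and transporter list, 1 of 27 fell, the metabotropic receptor GRM7, at -0.26 ± 0.061 (SE, adjusted p = 0.0251), and 26 did not pass (6 passed when adjusted over the list alone). The camera adjusted p was 0.0388, and the adjusted p = 0.514 with an estimated correlation. That call was lost in 7 of 11 alternatives, with TMM factors among them (adjusted p = 0.0928), and in 8 of the 14 fits that left out 1 library. GRM7 lost its call with each of the 4 other scalings (adjusted p = 0.0538 with TMM factors) and in 5 of the 14 fits that left out 1 library. SLC1A2, a glutamate transporter, measured 308 CPM ± 21.3 (SD, n = 7) in control and 272 CPM ± 16.2 (SD, n = 7) in lens retinas (adjusted p = 0.062). In the ganglion cell list, 1 of 19 fell, the neurofilament NEFM, at -0.37 ± 0.082 (SE, adjusted p = 0.0192), and 18 did not pass (1 passed when adjusted over the list alone). The camera adjusted p was 0.041, and the adjusted p = 0.717 with an estimated correlation. That call was lost with a filter of 10 CPM (adjusted p = 0.251) and in 8 of the 14 fits that left out 1 library. NEFL had -0.19 ± 0.067 (SE, adjusted p = 0.161). The cone list also passed as lower, with a camera adjusted p of 0.0062 and an adjusted p = 0.644 with an estimated correlation, and the rod list did not (camera adjusted p = 0.993). In the exact two-sided permutation test of list scores, 9 lists passed, all lower. The synaptic vesicle and heat shock scores each lost their call in 12 of the 14 tests that left out 1 library, and the voltage-gated channel score in 9. Lens 55 lay within the control range for the synaptic vesicle score (0.102) and the voltage-gated channel score (0.0665). Under each of 4 other scalings 1 list score passed, that of the known chick myopia genes.

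**Figure D3:**
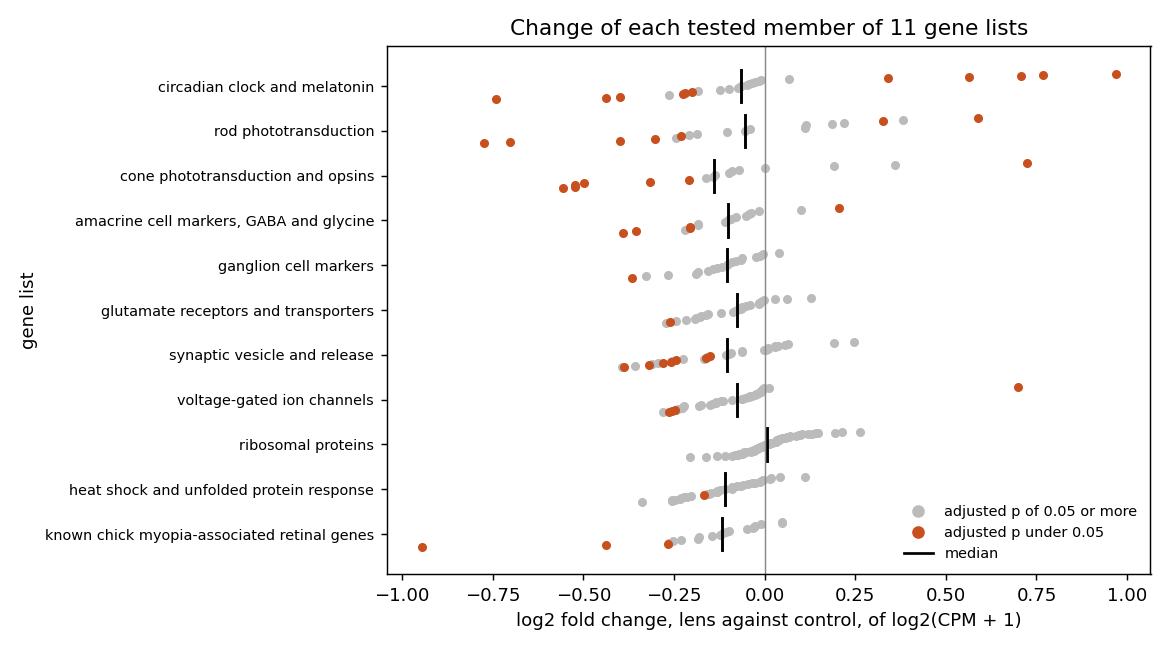
Each point is 1 tested gene of a list, placed by its log2 fold change of log2(CPM + 1), lens against control, and coloured orange where its adjusted p is under 0.05. Vertical black bars are list medians, for the clock and rod lists and the 9 lists that passed in camera, and the 7 synaptic vesicle genes past the threshold all lie below 0.

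Of 20 tested genes tied to chick myopia by earlier work, a list fixed before the data were examined, 3 fell, 0 rose and 17 did not pass (5 passed when adjusted over the list alone). Camera gave an adjusted p of 0.0062, and the adjusted p = 0.101 with an estimated correlation. The list score fell from 0.085 ± 0.045 (SD, n = 7) to -0.085 ± 0.023 (SD, n = 7) on the log2 scale (exact permutation adjusted p = 0.00699). The 3 that fell were RBP4, PER2 and GCG, the preproglucagon gene, which measured 13.9 CPM ± 0.605 (SD, n = 7) in control and 11.4 CPM ± 1.52 (SD, n = 7) in lens retinas (adjusted p = 0.0482). The GCG call was lost with TMM factors (adjusted p = 0.131), within a range of 0.0313 to 0.199 over its alternatives, and in 12 of the 14 fits that left out 1 library. PENK, the enkephalin precursor, had -0.23 ± 0.073 (SE, adjusted p = 0.111), and EGR1, an immediate early gene used as a marker of defocus sign, had -0.26 ± 0.20 (SE, adjusted p = 0.574). VIP, TH and BMP2 were under 1 CPM on average and were not tested with the other genes. VIP measured 0.755 CPM ± 0.163 (SD, n = 7) in control and 0.499 CPM ± 0.0968 (SD, n = 7) in lens retinas (exact permutation p = 0.00408, 1 of 3 such genes). The chick myopia list shares PER2, CRY1, OPN4 and MTNR1A with the clock list. As the labels give no time of day, a lens effect and collection time cannot be told apart for these shared genes either. The list score without them was not tested.

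The heat shock list passed as lower and the ribosomal protein list as higher in camera at the preset correlation, and neither passed with an estimated correlation (adjusted p = 0.717 and 0.984). In the heat shock and unfolded protein list, 1 of 35 members fell, the mitochondrial chaperone HSPA9, at -0.17 ± 0.040 (SE, adjusted p = 0.0306), and 34 did not pass (1 passed when adjusted over the list alone). Camera gave an adjusted p of 0.0062, and that call was lost in 2 of the 14 fits that left out 1 library (adjusted p up to 0.0636). HSPA2 measured 16.3 CPM ± 2.91 (SD, n = 7) in control and 12.6 CPM ± 1.58 (SD, n = 7) in lens retinas (adjusted p = 0.0915). The HSPA9 call was lost with TMM factors (adjusted p = 0.164), within a range of 0.0167 to 0.164 over its alternatives, and in 7 of the 14 fits that left out 1 library. The ribosomal protein list passed as higher relative to other genes (camera adjusted p = 0.0284), with an adjusted p = 0.984 with an estimated correlation. Of its 72 members 0 passed in limma, 0 with voom weights, 2 at an unadjusted p under 0.05, and its median log2 fold change was 0.0060. The call was lost in 4 of 11 alternatives and in 6 of the 14 fits that left out 1 library (adjusted p up to 0.3). Without the 3 libraries that lack W-linked transcripts the median was -0.0043 (camera adjusted p = 0.114). RPS12, at 0.21 ± 0.071 (SE, adjusted p = 0.137), did not pass.

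The tested markers of other cell types did not separate the groups, but many markers were not tested. Over 7 lists for pigment epithelium, vessels, blood, microglia, oligodendrocytes, lens and connective tissue, 0 of 46 tested genes passed in limma, 0 with voom weights and 5 at an unadjusted p under 0.05. Tested members were 10 of 24, 5 of 24, 1 of 22, 5 of 24, 9 of 20, 9 of 27 and 7 of 25, in that order. When adjusted over the list alone, 1 gene passed for pigment epithelium and 1 for blood. A difference in these cells can therefore have been missed. The largest axis of variation among libraries followed the sex chromosomes. Component 1, with 31.3% of the variance, set apart control 65, lens 48 and lens 55 at -23.9 to -20.5 from the other 11 libraries at 4.96 to 7.0. In those 3 libraries the W-linked gene HINTW measured 0.0929 to 0.598 CPM, against 117 to 147 CPM in the other 11, and of the 300 genes with the largest weights 234 lay on Z and 30 on W. Component 1 did not separate control from lens (exact two-sided permutation adjusted p = 0.947). Component 2, with 12.6% of the variance, averaged 6.14 ± 4.41 (SD, n = 7) in control and -6.14 ± 4.97 (SD, n = 7) in lens libraries (exact two-sided permutation adjusted p = 0.0035). The labels do not give sex. Without those 3 libraries 252 genes passed, 80 higher and 172 lower, of which 206 were among the 307.

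**Figure D4:**
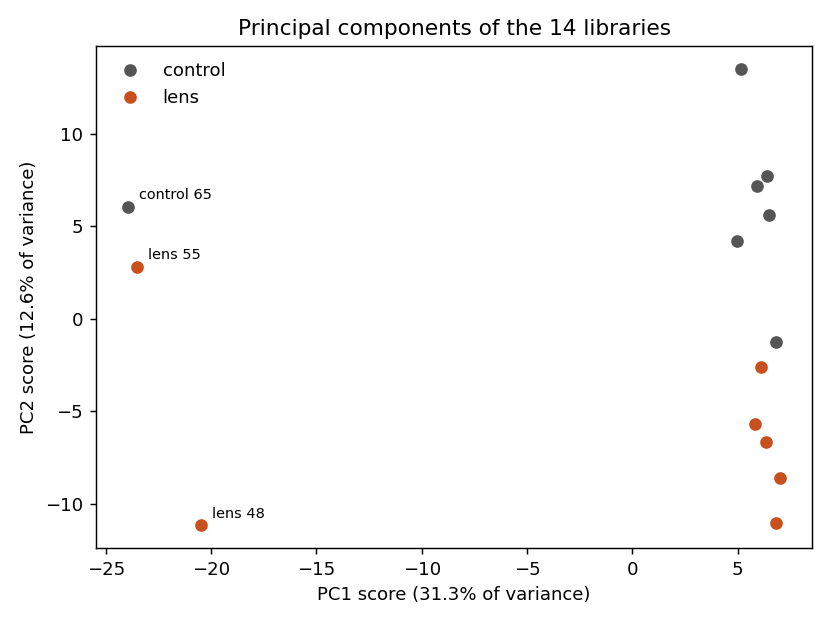
Each point is 1 of the 14 libraries, placed by its score on component 1 (31.3% of variance) and component 2 (12.6% of variance) of log2(CPM + 1) over tested genes. The 3 named libraries lie below -20 on component 1 and lack W-linked transcripts, and control libraries lie mostly above lens libraries on component 2.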

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

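The tests of chance splits in this part were chosen before the data were examined, and all other tests of explanations in it were chosen after the results were seen. Each group of 7 was checked for a library far from the other 6, by its gap to the nearest one as a share of the whole range. Of 210 groups 18 had such a library, where chance gives about 1 in 20 groups. Among genes, the shares were 0.62 for NEFM in lens 55 (35.5 CPM against 22.0 to 27.1 in the other 6), 0.658 for PDE6B in lens 48 (77.9 against 48.5 to 58.6) and 0.641 for PENK in lens 48 (16.3 against 14.5 to 15.1). They were 0.636 for SLC4A11 in control 65 (12.7 against 15.7 to 17.4) and 0.591 for TFAP2B in lens 53 (59.3 against 66.4 to 71.2). They were 0.609 for ARNTL2 in control 63 (41.6 against 33.0 to 36.4) and 0.589 for ABCA4 in lens 54 (270 against 226 to 244).

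Among list scores, lens 55 lay above the other lens libraries for starburst and cholinergic genes (0.639), ganglion cell markers (0.711), Wnt signalling (0.719), synaptic vesicle genes (0.638) and voltage-gated channels (0.62). Lens 47 lay below for retinoic acid genes (0.684), lens 48 below for glutamate receptors (0.582) and lens 54 below for heat shock genes (0.569). Control 58 lay below for microglia markers (0.688) and control 59 above for oligodendrocyte markers (0.626). Control 65 lay apart on component 1 (0.939), as the 1 control library that lacks W-linked transcripts.

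Whether any grouping of the libraries gives as many calls was tested by splitting the 14 libraries into 7 and 7 in 100 ways, the real one included. Of these, 1 reached the real count of 307 changed genes (highest other 2), 1 reached the 102 genes in the smaller direction (highest other 0), 1 reached the 205 in the larger direction (highest other 2) and 1 reached 9 gene lists (highest other 7). Most of the other splits called at least 1 list, and a split that called 0 genes called 7 lists. List calls at the preset correlation thus arose under other groupings far more readily than gene calls.

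Clock genes moved in opposite directions between the groups, and of 296 changed genes outside the clock list, 69.26% (205) had the sign that their slope on the clock axis among the control libraries predicts (exact permutation p = 0.00377 over 5040 orders), which is consistent with a difference in time of collection. Over all 11107 tested genes outside the clock list the share was 49.3% among controls (exact permutation p = 0.573), and among the lens libraries that of the 296 was 51% (exact permutation p = 0.434). All 11 clock calls remained with W-linked expression as a covariate, against an effect of the 3 libraries without it. The clock axis (raised minus lowered clock genes, log2) varied within each group, from -0.787 to -0.262 in control and from 0.254 to 0.706 in lens libraries. The labels give no time of collection, so an effect of the lens on the clock, a difference in collection time and any other influence on these genes all stay open.

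Photoreceptor genes moved in both directions. Of all 35 tested rod and cone genes 65.7% had a negative change, against 65.05% of all tested genes, and 55.6% of 10000 random gene sets had as many. Fewer photoreceptor cells would not raise the 3 genes that rose, but stay open for the 11 that fell. Of the 14 changed rod and cone genes, 92.86% (13) had the sign of their clock slope among controls (exact permutation p = 0.0355), which is consistent with collection time, and 42.9% did so among lens libraries (exact permutation p = 0.721). A lens effect and collection time stay open as well, with a share of 49.3% over all 11107 genes as above.

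The 8 gene lists that camera called lower in lens retinas hold 203 tested genes of amacrine and ganglion cells, synapses, channels, glutamate receptors, cones, heat shock and chick myopia. With each of the 4 other scalings camera lost the glutamate list and kept the other lists called lower. The per-library scores of 6 of these lists passed with the values as deposited and 1 after quantile normalization. The synaptic vesicle score difference went from -0.12 to -0.08 after that normalization. Scaling therefore stays open for the scores that no longer passed. Random sets of other genes matched on genomic span and level had a median change of -0.03 (10000 sets, lowest -0.07), against -0.10 for the 203 genes (percentile 0). The lists were picked as lower, which by itself places their genes below random sets. The comparison therefore cannot decide on a trend with span or level, and it is no test of the lists themselves. With an estimated correlation among members 0 lists passed, so the calls rest on the preset correlation.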

How the results depend on the processing

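MEIS2, SLC6A9, GJD2 and KCNH1 were not followed singly through the alternatives. Over 18 alternatives no other named gene reversed direction; of the comparisons per gene, 1002 kept their side of the threshold, 98 fell short of it and 5 newly passed, and with 1 library left out these counts were 813, 50 and 5. With TMM factors 110 genes were lower and 1 list score passed; with median-of-ratios factors 158 were higher, 107 lower and 1 list score passed. After quantile normalization 157 were higher, 122 lower and 1 list score passed, and with a common sum over listed genes 129 were lower and 1 list score passed. The exact permutation test per gene called 62 higher, 108 lower and 170 in all. These 170 were the genes at the smallest exact p that this design can give (exact permutation p = 5.83e-04, adjusted p = 0.0382). In these data no gene whose groups overlapped passed in it, which the design alone did not fix. That test ended the calls of PDE6B, CNGB1, RP1, MAFA, ARR3, NPAS2, CPLX1, CPLX4, KCNB2 and NEFM (exact permutation adjusted p = 0.0519 to 0.0983). The calls of OPN1LW, CRY2, GRM7, SLC32A1, GCG, SLC24A2, RDH8 and RGS9 were lost as well (exact permutation adjusted p = 0.0519 to 0.115). With a 1.5-fold minimum 13 were higher, 11 lower and 24 in all, with 16 named genes, by construction. At an adjusted p of 0.1, 374 were lower and 526 in all, by construction. With an estimated correlation camera called 0 lists. Leaving out 1 library gave 83 to 110 genes higher, 146 to 324 lower, 236 to 434 in all, 25 to 29 named genes, 5 to 10 lists in camera and 4 to 14 list scores. The highest counts of lower genes and of list scores came without lens replicate 55, and the 5 lists without lens replicate 54. List scores fell to 4 or 5 without control replicates 57, 59, 62, 64 or 65 or lens replicates 46 or 47. Apart from the thresholds and the smallest p of the exact test, the cause was not tested. Voom weights (296 genes), the common sum and leaving out the 3 libraries without W-linked transcripts (252 genes) were chosen after seeing the data. edgeR and DESeq2 were not run, because the values are not whole reads. In every setting in which components were recomputed, 1 of the first 3 components separated the groups. Which component it was in each setting was not recorded. The blood list (1 tested gene) and the mitochondrial list (0 tested) were too small to test. Genes under 1 CPM, below 32.3 to 42.6 reads, were mostly left untested.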

Other observations

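The genes in this paragraph fell outside the naming rule and were chosen after their values were seen. C2orf71, a photoreceptor cilium gene, had the smallest p of all tested genes. It went from 159 CPM ± 5.76 (SD, n = 7) to 117 CPM ± 3.31 (SD, n = 7), a log2 fold change of -0.45 (adjusted p = 1.39e-06). LOC101749116 had the largest change, 1.78 (adjusted p = 1.10e-04), from 1.63 CPM ± 0.890 (SD, n = 7) to 7.86 CPM ± 2.40 (SD, n = 7). Its log2 fold change ranged from 0.945 to 2.40 over its alternatives. NDRG1, a hypoxia-responsive gene, rose by 0.63 (adjusted p = 5.87e-05) as the only changed member of 22 tested hypoxia genes (1 when adjusted over the list alone). The growth factor PTN rose by 0.43 (adjusted p = 1.95e-04), from 523 CPM ± 35.5 (SD, n = 7) to 706 CPM ± 55.6 (SD, n = 7). The retinoid transporter ABCA4 rose by 0.36 (adjusted p = 2.54e-04). The interphotoreceptor matrix gene IMPG1 had -0.35 (adjusted p = 0.00215), the secretogranin SCG2 -0.32 (adjusted p = 0.00116) and the complexin CPLX1 -0.26 (adjusted p = 0.00983).

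The share of WDCP in the sum of WDCP and WDCPL was 22.2% ± 3.75 (SD, n = 7) in control and 39.6% ± 4.09 (SD, n = 7) in lens retinas (exact permutation p = 5.83e-04, the smallest this design can give). In all 7 lens retinas WDCP lay above every control and WDCPL below every control. That p was therefore fixed once the 2 genes were paired, and it adds no evidence. Among controls the genes of the clock list that rose and those that fell with the lens were opposed across libraries, with a Pearson r of -0.918 (exact permutation p = 0.00556, adjusted p = 0.0111) and a Spearman rho of -0.929 (exact permutation p = 0.00675), and r was -0.798 without the 2 farthest libraries. Among lens libraries r was -0.466 (exact permutation p = 0.290) and rho -0.50 (exact permutation p = 0.267), and r was 0.392 without the 2 farthest libraries.

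Changed genes of 1 direction that lie next to each other formed 10 pairs, in a test chosen after the results were seen. Over 10000 random placements the mean was 4.10 and the highest 12, and 0.88% had as many.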
